A study of Homo sapiens with 11 samples.

How the data were processed

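The series measured polyadenylated RNA of HEK293T cells, a human embryonic kidney line that carries the SV40 large T antigen. Per the labels' protocols, strand-specific libraries were made with dUTP marking of the second strand and were sequenced on a DNBSEQ instrument. Samples were grouped by the treatment given in their labels into vehicle (DMSO, n = 3), vehicle with ISRIB (n = 2), the compound A8 at 10 µM (n = 3) and A8 with ISRIB (n = 3). The series' design text calls the replicates biological. Per the labels, replicate 2 of the vehicle with ISRIB group was excluded by the submitters for poor quality. The sample titles give a treatment time of 8 h, while the treatment protocol gives 4 h, and the labels do not settle which holds.

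The deposited count table holds whole-number counts per gene symbol for 27671 genes and 11 libraries, of which 6426 genes had 0 counts in all libraries. The genome build was GRCh37 and the tools named are DESeq and DESeq2, per the submitters' processing notes. The aligner, the counting program, its strand setting and the annotation are not given in the sources used here. No coordinates are printed, because the reference annotation at hand was of another build and served only for gene names and for the GC content of transcripts. The authors also deposited 3 DESeq2 results tables of 20395 genes each, with base means (a signal of normalized counts), log2 fold changes and adjusted p-values, per the file headers. Only 7.69% of the authors' deposited base means were within 1% of those computed from the 11 count columns, so the set of libraries in the authors' fit is not known, and their tables were set beside the present fit and never pooled with it.

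Counts per library summed to between 34072107 and 35318111. At this depth a count of 0 allows up to 0.0881 CPM (counts scaled to a common library total) in the shallowest library, taken as 3 counts. Such limits cover counting error only, while intervals of fold changes rest on standard errors that include the spread between libraries. Replicates of each group differed by more than sampling noise, with chi-square values per degree of freedom of 7.36 to 37.0 over genes, so no library was counted as a copy of another. The 2 columns of the vehicle with ISRIB group carry numbers that differ from those in the sample titles, so these libraries were given to the group only and are called a and b.

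Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the groups, which left 15591, and libraries were scaled with TMM. All 11 libraries entered one quasi-likelihood fit of group means (glmQLFit and glmQLFTest), so that the group of 2 shared the estimate of the spread. Adjusted p-values are Benjamini-Hochberg values over all genes tested, and a gene was called at an adjusted p under 0.05. The standard error (SE) of a log2 fold change was derived from the quasi-likelihood F statistic. Levels are TMM-scaled CPM, given as mean ± SD over libraries. Genes with near-identical copies, such as HSPA1A and HSPA1B, could share reads in a way the deposited counts do not show.

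In all 6 comparisons were made, namely A8, ISRIB and both together against vehicle, A8 with ISRIB against ISRIB alone, A8 with ISRIB against A8, and the interaction, which asks whether the effect of A8 differs with ISRIB. Gene lists of stress pathways, interferon and inflammatory genes, cell cycle, mitochondrial, ribosomal and histone genes, and markers of other cell types were fixed before the data were examined, and 346 of their 346 members were matched to symbols in the table. The 4 lists of the integrated stress response were also pooled, giving 23 lists. The list of markers of other cell types entered the tests and their adjustment, and its result is not reported here. Lists were tested against all other genes with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 23 lists. Estimated correlations and fry, a rotation test that asks whether a list moves one way, were the alternatives.

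Genes were named by a rule fixed at the same time. It names 16 stress and antiviral genes in every comparison, the 8 called genes with the largest rise and the 8 with the largest fall in A8 against vehicle, 4 and 4 in the other comparisons, and up to 4 called members of each list. Not all of their values are printed below. Genes taken by size had a mean log2 CPM of at least 2 and no overlap between the libraries of both groups, except in the interaction. Genes named outside this rule were chosen after their values were seen.

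Alternatives fixed with these rules were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter on low counts, a filter of at least 50 counts, a replicate block, fits of only the groups compared, each library left out in turn, and a minimum absolute log2 fold change of 1. A robust quasi-likelihood fit, removal of each library's trend along GC content by lowess with a span of 0.3, a fit without the DMSO 1 and DMSO with ISRIB b libraries, and a fit without both ISRIB-only libraries were added after seeing the data. GC content was known for 87.8% of the genes tested.

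The fits were tested on simulated counts drawn from the real means, spreads and library sizes over 15591 genes. For A8 against vehicle, edgeR called 13.4% of genes changed 1.25-fold, 67.2% of those changed 1.5-fold and 80.3% of those changed 2-fold, and 9 of its 116 calls were unchanged genes. For ISRIB alone against vehicle it called 5.97%, 58.2% and 69.7%, and for the interaction 1.49%, 38.8% and 65.2%. In the simulation of A8 against vehicle, 16 of 130 calls by DESeq2 were unchanged genes. A simulated list of 54 genes raised 1.25-fold was called, and none of 19 unchanged lists was. Simulated genes varied independently, so this run does not show how the preset correlation serves lists whose genes vary together.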

Results

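Transcripts of HEK293T cells were counted after treatment with A8, a compound that the series title links to RIG-I and to the integrated stress response. RIG-I, encoded by DDX58, is a cytosolic sensor of viral RNA. The integrated stress response is the programme set off by phosphorylation of the translation factor eIF2, through which ATF4 induces genes of amino acid supply, and ISRIB is a small molecule that acts on eIF2B and blunts this response. There were 3 vehicle libraries, 2 with ISRIB alone, 3 with 10 µM A8 and 3 with A8 and ISRIB, each with 34072107 to 35318111 counts and 17892 to 18017 genes detected.

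The first question was what A8 did to the transcriptome relative to vehicle. A8 raised a set of genes of amino acid synthesis and stress signalling. CHAC1, which degrades glutathione and is a target of ATF4 and CHOP, rose from 5.22 ± 0.51 CPM (SD, n = 3) to 16.9 ± 3.7 CPM (SD, n = 3), a log2 fold change of 1.70 (SE 0.15). SLC6A9, a glycine transporter, rose from 28.8 ± 3.0 to 57.0 ± 8.0 CPM, a log2 fold change of 0.99 (SE 0.10). ASNS, the asparagine synthetase, rose from 157.8 ± 7.8 to 257.1 ± 20.4 CPM, a log2 fold change of 0.70 (SE 0.07). In the other direction TXNIP, an inhibitor of thioredoxin that restrains glucose uptake, fell from 9.48 ± 0.78 to 4.32 ± 0.53 CPM. Its log2 fold change was -1.13 (SE 0.15), and it was lower in each of the 3 A8 libraries than in any vehicle library.

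By edgeR's quasi-likelihood test 13 genes were higher and 9 lower with A8 among 15591 tested, while 1596 genes (10.2%) had an unadjusted p under 0.05. Among called genes with a mean log2 CPM of at least 2, the other large rises were those of PCK2, the mitochondrial form of PEP carboxykinase (log2 fold change 0.88), CTH, which makes cysteine from cystathionine (0.85), STC2, a secreted stress-induced glycoprotein (0.84), SESN2, a leucine-binding regulator of mTORC1 (0.63), and PSAT1, of serine synthesis (0.53), with adjusted p from 0.000131 to 0.00233 in edgeR. The genes that fell with TXNIP were its arrestin-family relative ARRDC4 (-0.68), the inducible chaperones HSPA1A and HSPA1B (-0.55 each), LOC101927883 (-0.52), the constitutive chaperone HSPA8 (-0.43), SRSF11 (-0.38), TPRA1 (-0.38) and the co-chaperone DNAJB1 (-0.34). HSPA1A and HSPA1B are near-identical copies, so their separate values are uncertain. Of the 22 calls, 13 were made in each of the 6 fits that left out 1 library, and none changed sign. The calls of ARRDC4, DNAJB1, GARS, HSPA8, LOC101927883, NUPR1, SRSF11, TPRA1 and ZC3H6, the last chosen after its value was seen, were lost in at least 1 of these fits, and the number of lower genes fell to 5 without DMSO 2, 4 without A8 1, 3 without A8 2 and 5 without A8 3. The DESeq2 Wald test called 63 genes higher and 69 lower, and edgeR without a filter on low counts called 59 and 45. Fold changes had a Spearman correlation of -0.29 with the GC content of transcripts across genes, which are not independent replicates, and 23 genes were higher once this trend was removed, an analysis chosen after seeing the data.

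**Figure D1:**
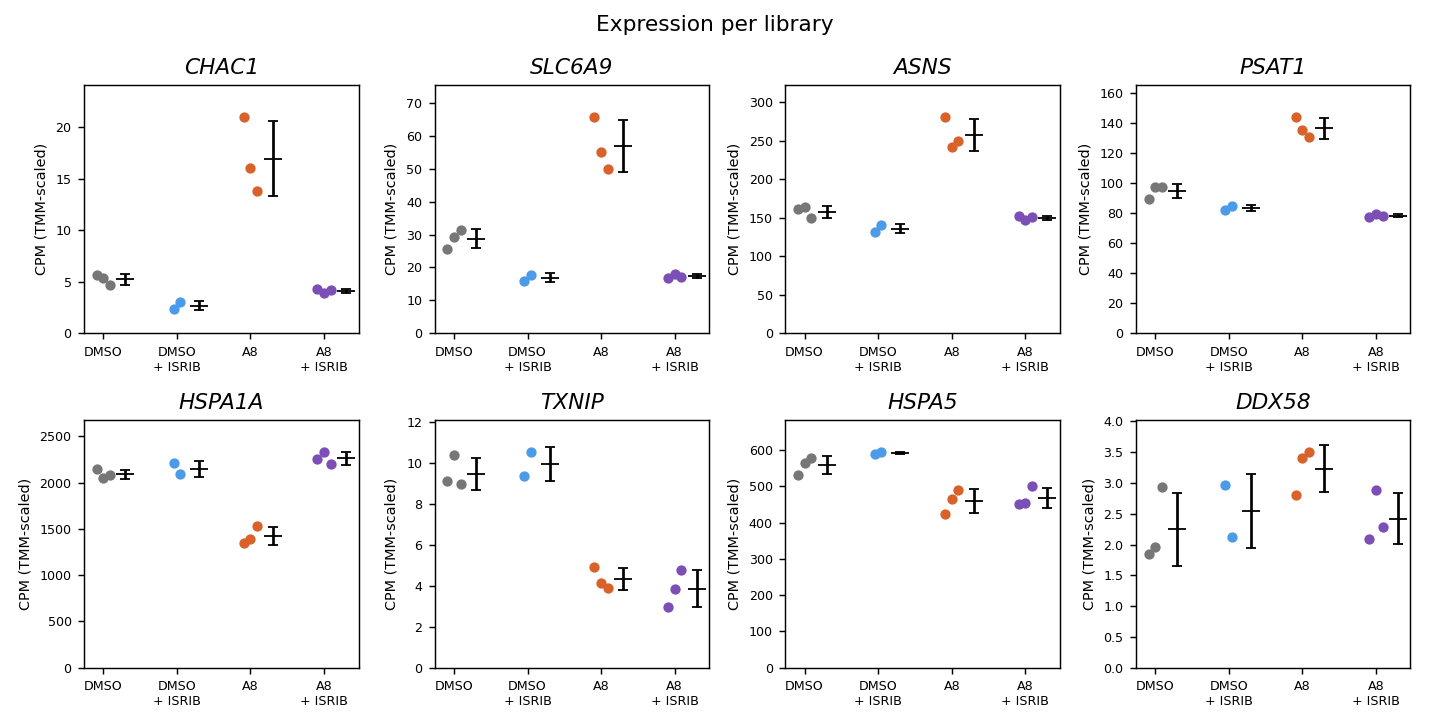
TMM-scaled CPM (vertical axis, from 0) of 8 genes in each library (points) of the 4 treatment groups (horizontal axis), with the mean and SD of each group beside the points. CHAC1 averaged 16.9 CPM with A8 and 4.11 CPM with A8 and ISRIB, whereas TXNIP averaged 4.32 and 3.87 CPM, both below its vehicle mean of 9.48 CPM.

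All 4 lists of integrated stress response genes were higher with A8. Of 54 measured members, 52 had a fold change above 0, 11 were called higher over all genes tested and 43 were not called. Adjusted over the list alone, 44 were higher and 1 was lower. The median log2 fold change was 0.31 for the pooled list, with a camera adjusted p of 2.29e-35, and the call held with an estimated correlation (adjusted p = 0.00604). Among regulators, with 4 of 19 called, CHAC1, STC2 and SESN2 were joined by NUPR1 (log2 fold change 1.39), a small stress-induced nuclear protein. The canonical transcription factors did not pass the test, with log2 fold changes of 0.24 for ATF4, 0.36 for DDIT3, which encodes CHOP, and 0.48 for ATF3, and the pseudokinase TRIB3 had a value of 0.18 (adjusted p from 0.181 to 0.583 in edgeR). The 95% intervals of ATF4 (0.08 to 0.41), DDIT3 (0.11 to 0.60) and ATF3 (0.24 to 0.73) excluded 0, while that of TRIB3 (-0.025 to 0.376) did not. Of 13 amino acid synthesis genes 4 were called, ASNS, CTH, PSAT1 and the mitochondrial folate enzyme MTHFD2 (0.44). Of 9 transporters 1 was called, SLC6A9, while SLC7A11, the cystine carrier, had a log2 fold change of 0.80 (SE 0.24) and an adjusted p of 0.246 in edgeR. Of 13 tRNA synthetase genes 2 were called, CARS (0.46) and GARS (0.34). The medians of the lists were 0.39 for regulators, 0.33 for synthesis, 0.45 for transport and 0.24 for tRNA synthetases, each called by camera and with an estimated correlation (adjusted p from 0.00441 to 0.0377). Adjusted over the list alone, 14 regulators, 8 synthesis genes, 9 transporters and 12 tRNA synthetase genes were higher, and 1 regulator was lower.

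The heat shock list was lower with A8, with a median of -0.18 and a fold change below 0 for 14 of its 14 members. The camera adjusted p was 1.36e-10, and 0.0462 with an estimated correlation. HSPA1A, HSPA1B, HSPA8 and DNAJB1 were the called members, and 6 members were lower adjusted over the list alone. HSPA1A went from 2091 ± 48 CPM (SD, n = 3) to 1425 ± 95 CPM (SD, n = 3).

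Neither list of the unfolded protein response of the endoplasmic reticulum was called higher. The ATF6 list, of chaperones of that compartment, had a median of -0.15 with 0 of 11 members called over all genes tested, and 1 higher and 8 lower adjusted over the list alone. Its camera adjusted p was 0.00022, a call that was lost with an estimated correlation (adjusted p = 0.175). HSPA5, which encodes the chaperone BiP, had a log2 fold change of -0.28 (SE 0.07, adjusted p = 0.124 in edgeR). For the XBP1s list the median was 0.04 (camera adjusted p = 0.829), and DNAJB9 had a value of 0.04. No member of the NRF2, interferon, NF-kB or p53 lists was called over all genes tested, and camera adjusted p-values were 0.676, 0.777, 0.829 and 0.719. Adjusted over the list alone, 1 NRF2 gene was lower and 0 were called in the other 3 lists. For the NRF2, interferon and p53 lists the median lay above 0 while the mean and the camera direction lay below. HMOX1, the heme oxygenase induced by oxidative stress, had a log2 fold change of 0.20 (SE 0.08, adjusted p = 0.392 in edgeR).

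None of the antiviral genes named here was called. IFNB1, the interferon beta gene, had 0 counts in all 11 libraries, which allows up to 0.0881 CPM, and IL8, the symbol in the table for CXCL8, had 0 to 8 counts per library. Both were below the filter and were not tested, as were 12 of the 30 interferon list members and 8 of the 16 NF-kB list members. IFIT1, an interferon-induced gene, measured 2.51 ± 0.43 CPM in vehicle (SD, n = 3) and 1.83 ± 0.38 CPM with A8 (SD, n = 3). DDX58 itself measured 2.25 ± 0.59 CPM in vehicle and 3.23 ± 0.38 CPM with A8, a log2 fold change of 0.52 with a 95% interval of 0.11 to 0.94 and an adjusted p of 0.413 in edgeR. For IFIT1 the log2 fold change was -0.46 with a 95% interval of -0.86 to -0.06 and an adjusted p of 0.449. Both intervals excluded 0, and neither gene passed the adjustment over 15591 genes. An unadjusted p under 0.05 in edgeR was reached by 10.2% of all genes tested, so such intervals are weak evidence for a single gene.

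The authors' deposited table for the same comparison listed 46 genes higher and 19 lower at an adjusted p under 0.05. The higher ones included KTI12 (log2 fold change 18.9), which had 0 counts in every vehicle library and also in A8 3. Among the 22 genes called here, 21 were among those of the authors' deposited table, and fold changes across genes had a Pearson correlation of 0.94 with it. In the authors' deposited table CHAC1 had a log2 fold change of 1.70, ATF3 one of 0.48 with an adjusted p of 0.0494, and HSPA5 one of -0.28 with an adjusted p of 0.00992.

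ISRIB alone was compared with vehicle to see what the inhibitor did without A8. By edgeR no single gene was called, and camera called integrated stress response lists lower only with its preset correlation (adjusted p from 0.337 to 0.449 with an estimated correlation). CHAC1 averaged 2.67 ± 0.46 CPM with ISRIB (SD, n = 2), a log2 fold change of -0.97 (SE 0.19), and SLC6A9 averaged 16.9 ± 1.4 CPM (SD, n = 2), a log2 fold change of -0.77 (SE 0.12, adjusted p = 0.0897 in edgeR). The pooled list had a median of -0.14, with 45 of 54 members below 0, and a camera adjusted p of 4.04e-08, which was lost with an estimated correlation (adjusted p = 0.337). Adjusted over the list alone, 10 members were lower. Camera also called the regulators (median -0.25), the synthesis list (-0.14) and the transport list (-0.15), and these calls too were lost with an estimated correlation (adjusted p = 0.337, 0.449 and 0.347). For tRNA synthetases the median was near 0 and the camera adjusted p was 0.913. The count of 0 higher and 0 lower genes by edgeR stood against 1494 genes at an unadjusted p under 0.05, and the DESeq2 Wald test called 5 higher and 46 lower. With edgeR 1 gene was higher and 2 lower without DMSO 1, and 1 was higher without DMSO with ISRIB a. The authors' deposited table listed 1 gene higher and 7 lower, 5 of which belong to the integrated stress response lists. Another of the 7 was NBL1 (log2 fold change -24.4), which had 0 counts in DMSO with ISRIB a and b and is taken up under other observations. Fold changes in this comparison followed the GC content of the transcripts, with a Spearman correlation of -0.47 across genes.

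A8 with ISRIB was then compared with A8 alone, which asks what ISRIB did where A8 was present. ISRIB lowered 12 of the 13 genes that A8 had raised. These falls also hold what ISRIB does without A8, so they do not by themselves measure a loss of the A8 effect. NUPR1, one of the 12, had a log2 fold change of -1.6 (SE 0.38, adjusted p = 0.316 in edgeR) with ISRIB alone. Its rise with A8 was 1.39 without ISRIB and 1.47 with it. SLC6A9 fell from 57.0 ± 8.0 to 17.3 ± 0.6 CPM (SD, n = 3 each), a log2 fold change of -1.72 (SE 0.10), and CHAC1 fell from 16.9 ± 3.7 to 4.11 ± 0.22 CPM, a log2 fold change of -2.05 (SE 0.15). DDIT4, an inhibitor of mTORC1, had a log2 fold change of -1.17 (SE 0.13) and PCK2 one of -1.10 (SE 0.10). HSPA1A, HSPA1B and DNAJB1 rose, by log2 fold changes of 0.67, 0.67 and 0.33. In all 25 genes were lower and 3 higher in edgeR, 21 of the lower ones from the integrated stress response lists. The pooled list had a median of -0.33 (camera adjusted p = 2.19e-51, and adjusted p = 0.00188 with an estimated correlation), and all 4 of its parts were called both ways. Amino acid synthesis had 6 of 13 members called lower, transport 5 of 9, regulators 6 of 19 and tRNA synthetases 4 of 13. ATF4, DDIT3, ATF3 and TRIB3 had log2 fold changes of -0.25, -0.40, -0.43 and -0.34 and were not called (adjusted p from 0.488 to 0.601 in edgeR). Their 95% intervals lay below 0 (-0.41 to -0.08, -0.65 to -0.15, -0.67 to -0.19 and -0.55 to -0.14). With ISRIB alone, however, ATF4 had a log2 fold change of -0.33 (SE 0.10, adjusted p = 0.368 in edgeR), and its interaction was 0.08 (SE 0.13). The fall of ATF4 is therefore no sign that ISRIB weakened the effect of A8 on it. Interactions of DDIT3, ATF3 and TRIB3 were -0.15, -0.37 and -0.12. None of the 4 interactions was called (adjusted p from 0.63 to 0.892 in edgeR). The heat shock list was higher with a median of 0.09 (camera adjusted p = 6.3e-09), a call lost with an estimated correlation (adjusted p = 0.0612). Of the 28 calls, 16 were made in each of the 6 fits that left out 1 library, and without A8 1 the number of lower genes was 14. The DESeq2 Wald test called 15 higher and 38 lower.

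The 12 genes called in both are a count to be set against chance, as are the 3 of 9 lower genes that were called higher when ISRIB was added. Both comparisons use the A8 libraries, so chance deviations of these libraries act in opposite directions in them. In 20 simulations with no effect of A8 or ISRIB at most 1 gene was called in both in either direction. Independent lists of these sizes would share 0.021 and 0.0017 genes. The simulated counts held no A8 response and no variation shared between genes. They therefore cannot show how many genes the shared libraries alone would bring into both where A8 acts. The group of 3 A8 libraries could not be split into parts of 2, so part of the excess may come from the shared libraries.

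Whether the A8 response remained with ISRIB was measured in A8 with ISRIB against ISRIB alone, which shares no library with A8 against vehicle. The 13 genes called higher with A8 had a median log2 fold change of 0.84 without ISRIB and 0.14 with it. Those without ISRIB are inflated by the choice of genes and those with it are not. ASNS had a log2 fold change of 0.14 with ISRIB, PSAT1 one of -0.09 and CHAC1 one of 0.62 (SE 0.19), none of them called (adjusted p from 0.414 to 0.76 in edgeR). NUPR1 had one of 1.47 (SE 0.38), STC2 one of 0.44 (SE 0.10) and SESN2 one of 0.23 (SE 0.08). They were not called either (adjusted p from 0.251 to 0.516 in edgeR), and NUPR1 had only 9 and 14 counts in the ISRIB-only libraries. Of the 13 genes, 11 had a fold change above 0 with ISRIB. The 9 genes called lower had medians of -0.52 and -0.28, and 5 of the 9 had a fold change below 0 with ISRIB too. That median stands between genes that stayed lower, such as TXNIP (-1.37) and ARRDC4 (-0.82), and genes that did not, such as HSPA1A (0.07). With genes called anew without 1 library, the value with ISRIB of the higher genes was 0.0455 without DMSO 1, 0.0432 without DMSO 2, 0.0463 without DMSO 3, 0.0952 without DMSO with ISRIB a, 0.094 without A8 1, 0.0483 without A8 2, 0.194 without A8 3 and 0.0683 without A8 with ISRIB 2. That of the lower genes turned to 0.0725 without DMSO 2, 0.0455 without A8 1, 0.0723 without A8 2 and 0.0302 without A8 3, and was -0.1298 without DMSO 3, -0.1804 without DMSO with ISRIB b, -0.0518 without A8 with ISRIB 1 and -0.0012 without A8 with ISRIB 3. TXNIP fell by 1.37 on the log2 scale (SE 0.17, adjusted p = 0.00412 in edgeR), from 9.96 ± 0.82 CPM (SD, n = 2) to 3.87 ± 0.90 CPM (SD, n = 3). PTP4A3, a phosphatase that lay below the level set by the naming rule and was chosen after its value was seen, was the only gene called higher, with a log2 fold change of 1.05 (SE 0.16). The call of TXNIP was lost when DMSO with ISRIB b or A8 with ISRIB 2 was left out, and that of PTP4A3 when any of 4 libraries was left out, namely DMSO with ISRIB a or b or A8 with ISRIB 1 or 2. There were 2 genes lower without DMSO with ISRIB a, and 5 higher and 8 lower without A8 with ISRIB 3. DESeq2 called 48 higher and 20 lower. The pooled stress response list had a median of 0.06 (camera adjusted p = 0.00175, lost with an estimated correlation, adjusted p = 0.373), and the regulators list one of 0.23 (camera adjusted p = 4.02e-07, lost likewise, adjusted p = 0.234). Above 0 were 42 of 54 members of the pool and 18 of 19 regulators. Adjusted over the list alone, 6 members of the pool and 8 regulators were higher. The lists of amino acid synthesis, transport and tRNA synthetases had medians of 0.02, 0.04 and 0.01 and were not called. The heat shock list had a median of -0.12 (camera adjusted p = 0.0375, lost with an estimated correlation, adjusted p = 0.592). For the ATF6 list it was -0.15 (camera adjusted p = 0.000541) and for the XBP1s list -0.10 (camera adjusted p = 0.00524). Both calls were lost likewise (adjusted p = 0.234). HSPA5 had a log2 fold change of -0.34 (SE 0.07), HMOX1 one of 0.34 (SE 0.09) and ATF4 one of 0.32 (SE 0.10). DDIT3 had one of 0.20, ATF3 one of 0.12 and TRIB3 one of 0.06. None of these genes was called (adjusted p from 0.211 to 0.935 in edgeR). Across all 15591 genes the fold changes of A8 without and with ISRIB had a Pearson correlation of 0.12 and a Spearman correlation of 0.05, and the Pearson value was 0.0603 without DMSO 3 and 0.0172 without DMSO with ISRIB a. The Spearman value ranged from -0.0114 without A8 1 to 0.092 without A8 with ISRIB 3. With the GC trend removed, an analysis chosen after seeing the data, the Pearson value was 0.1509 and the Spearman value 0.1598, and without a filter on low counts the Pearson value was 0.0372.

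**Figure D2:**
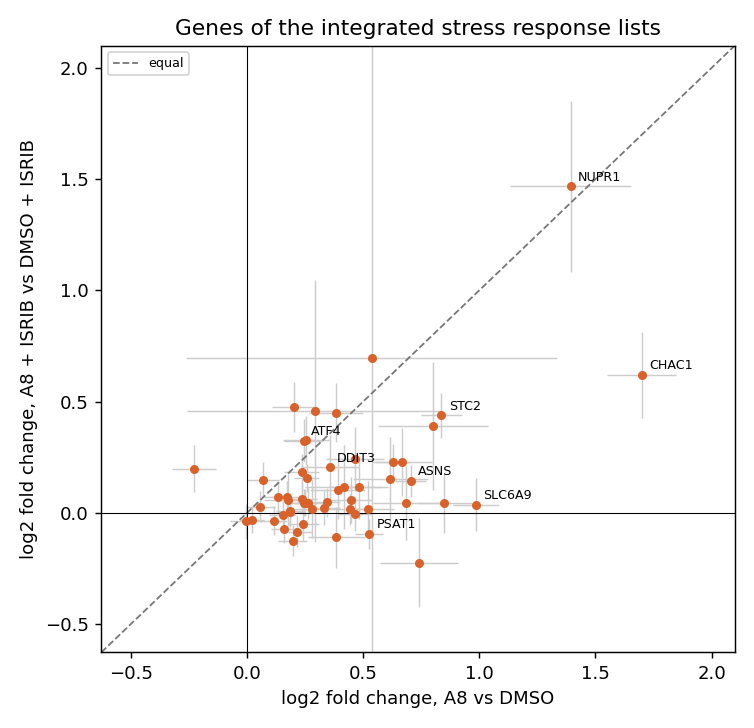
Log2 fold change of each of 54 integrated stress response genes in A8 against vehicle (horizontal axis) and in A8 with ISRIB against ISRIB alone (vertical axis). Bars are standard errors, that of FGF21 runs past the frame, and the dashed line marks equal values. The medians are 0.31 on the horizontal and 0.06 on the vertical axis.

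The test of the difference itself was the interaction. Here PSAT1 had a log2 difference of -0.62 (SE 0.09) and SLC6A9 one of -0.95 (SE 0.15). Both were called higher with A8 without ISRIB (log2 fold changes of 0.53 and 0.99), and neither was called in A8 with ISRIB against ISRIB alone (-0.09 and 0.04). HSPA1A had a difference of 0.63 (SE 0.09) and HSPA1B one of 0.64 (SE 0.09). Both were called lower with A8 without ISRIB (-0.55 each), and neither was called with it (0.07 and 0.09). These were the 4 genes called (adjusted p from 0.0243 to 0.0443 in edgeR). For CHAC1 the difference was -1.08 (SE 0.24, adjusted p = 0.241) and for ASNS -0.56 (SE 0.10, adjusted p = 0.0766). The pooled stress response list had a median of -0.23 with 45 of 54 members below 0 (camera adjusted p = 2.74e-13), a call lost with an estimated correlation (adjusted p = 0.0868). Of its parts, tRNA synthetases kept the call that way (median -0.22, adjusted p = 0.0208), while synthesis (-0.31), transport (-0.30) and regulators (-0.12) lost it (adjusted p = 0.0868, 0.0868 and 0.53). Each of the 4 gene calls was lost in at least 1 of 11 fits that left out a library, with 0 genes called in either direction without DMSO 2, DMSO with ISRIB b, A8 1, A8 2, A8 with ISRIB 1 or A8 with ISRIB 2. There was 1 higher gene without DMSO 1, and 0 higher and 1 lower without DMSO with ISRIB a. The regulators list lost its camera call without DMSO 3, DMSO with ISRIB b, A8 1 or A8 with ISRIB 1, with medians of -0.1084, -0.1836, -0.0559 and -0.1494. None of the 4 was called once the trend along GC content, with a Spearman correlation of 0.45 across genes, was removed, an analysis chosen after seeing the data. The differences were then -0.52 (SE 0.09) for PSAT1, -1.06 (SE 0.16) for SLC6A9, 0.51 (SE 0.10) for HSPA1A and 0.53 (SE 0.09) for HSPA1B (adjusted p from 0.0538 to 0.154 in edgeR). The DESeq2 Wald test called 42 higher and 9 lower.

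Both compounds together were finally set against vehicle, the third of the authors' deposited comparisons. TXNIP had a log2 fold change of -1.30 (SE 0.15), SLC6A9 one of -0.73 (SE 0.10) and TPRA1 one of -0.43 (SE 0.07), and these 3 genes were lower and 0 higher by edgeR, with 1200 genes at an unadjusted p under 0.05. By DESeq2 10 genes were higher and 19 lower. All 3 calls were lost when only the groups compared were fitted and in at least 1 of the fits without 1 library, and 0 genes were lower without A8 with ISRIB 2, 1 without DMSO 2, DMSO 3 or A8 with ISRIB 1, while 3 were higher without DMSO 1. The authors' deposited table listed 4 higher and 4 lower, among them the 3 called here. KTI12 was again among the higher ones (log2 fold change 19.1), with 0 counts in every vehicle library and also in A8 with ISRIB 1. ASNS had a log2 fold change of -0.07 (SE 0.07), CHAC1 one of -0.35 (SE 0.16) and HSPA1A one of 0.11 (SE 0.06), none of them called. The pooled stress response list had a median of -0.06 (camera adjusted p = 0.00764, lost with an estimated correlation, adjusted p = 0.342).

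**Figure D3:**
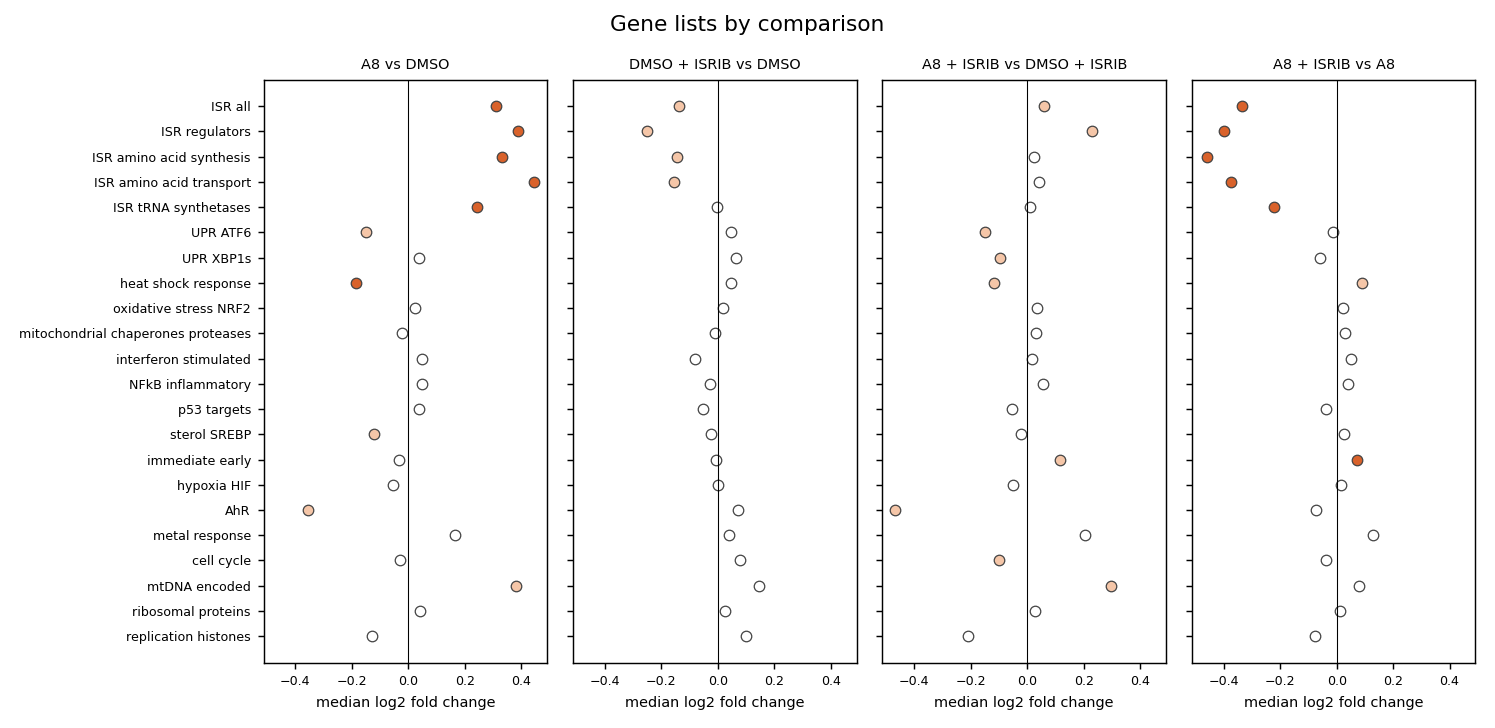
Median log2 fold change (horizontal axis) of each gene list but the markers of other cell types (vertical axis) in 4 comparisons. Dark points were called by camera with both the preset and an estimated correlation, pale points with the preset correlation alone and open points with neither. The pooled stress response list lies at 0.31 in A8 against vehicle and at -0.33 in A8 with ISRIB against A8.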

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

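The tests of GC content were chosen after the results were seen, and the splits of the libraries before. Results stand here because the effect of A8 differed with and without ISRIB in the interaction test. The single genes were PSAT1 (-0.62), SLC6A9 (-0.95), HSPA1A (0.626) and HSPA1B (0.638). The lists reported here, by camera with the preset correlation, were the pooled integrated stress response list with a median of -0.227, regulators with -0.117, amino acid synthesis with -0.31, transport with -0.301, tRNA synthetases with -0.22, the XBP1s list with -0.117, heat shock with 0.063, and immediate early genes with 0.139. Apart from tRNA synthetases, these list calls were lost with an estimated correlation (adjusted p from 0.0868 to 0.53).

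Fold changes in ISRIB alone against vehicle trended with GC content, with a Spearman correlation of -0.47 across genes, and so did the interaction, with 0.45. Libraries of one group differed along GC content too, the most being DMSO 1 against the rest of its group with a Spearman correlation of 0.343, which fits yield that differs between libraries. An effect of ISRIB on GC-rich genes stays open, since the correlation in A8 with ISRIB against A8 was 0.146, within the differences among libraries of those groups. With the trend removed the 4 interaction calls ended, as PSAT1 went from -0.62 (SE 0.09) to -0.52 (SE 0.09), HSPA1A from 0.63 (SE 0.09) to 0.51 (SE 0.10) and HSPA1B from 0.64 (SE 0.09) to 0.53 (SE 0.09), and SLC6A9 from -0.95 (SE 0.15) to -1.06 (SE 0.16) with an adjusted p of 0.0538 in edgeR. The differences of PSAT1, HSPA1A and HSPA1B became smaller, whereas that of SLC6A9 did not.

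Among the 10 splits of the 6 libraries of A8 and vehicle, 1 gave as many calls, the real one with 22, and the highest other gave 0. For A8 with ISRIB against A8 it was again 1 of 10, with 28 calls and 0. For both compounds against vehicle it was 2 of 10, with 3 calls for the real split and 454 for the split that put A8 with ISRIB 3 with DMSO 1 and DMSO 2, which points to a structure among the libraries other than treatment. With 10 splits there are too few for a share under 0.05.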

How the results depend on the processing

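The fits called robust, GC trend removed, without DMSO 1 and DMSO with ISRIB b, and without both ISRIB-only libraries were chosen after seeing the data. Counts of genes are given as higher and lower, and the causes were not tested unless stated. The 4 stress response lists and their pool kept direction and call in A8 against vehicle under every alternative run, with pooled medians of 0.2743 to 0.3577 when 1 library was left out. DESeq2 size factors changed none of the counts by over 1.5 times.

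The DESeq2 Wald test called 63 and 69 in A8 against vehicle, 5 and 46 with ISRIB alone, 10 and 19 with both against vehicle, 48 and 20 in A8 with ISRIB against ISRIB alone, 15 and 38 against A8, and 42 and 9 in the interaction. It gave no adjusted p for 16 of 112 values of named genes. Without a filter on low counts edgeR called, in the same order, 59 and 45, 3 and 11, 22 and 18, 28 and 13, 13 and 41, and 18 and 8. A log2 fold change of at least 1 left 3 and 1 in A8 against vehicle, 1 lower with both compounds, 0 and 6 in A8 with ISRIB against A8, and 0 and 0 in the interaction. With only the groups compared, ISRIB alone gave 1 and 2, both compounds gave 0 lower and A8 with ISRIB against ISRIB alone 0 higher. The filter at 50 counts gave 4 and 2 in the last comparison and 1 lower in the interaction, and the robust fit 4 and 2. With the GC trend removed 23 genes were higher in A8 against vehicle, 0 in A8 with ISRIB against ISRIB alone, and 0 and 0 in the interaction. Without DMSO 1 and DMSO with ISRIB b there were 4 lower in A8 against vehicle, 1 and 1 with ISRIB alone, 2 higher with both, 0 and 0 in A8 with ISRIB against ISRIB alone, and 1 and 0 in the interaction.

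The replicate block, fitted on the 9 libraries with numbers, gave 4 lower in A8 against vehicle, 0 lower with both compounds and 13 lower in A8 with ISRIB against A8, while the fit without both ISRIB-only libraries kept every count within 1.5 times. With the block 14 of the 22 calls in A8 against vehicle were kept, 15 of the 28 in A8 with ISRIB against A8, and 0 of the 3 with both compounds. The numbers gave no clear sign of pairing, since 1 of 9 same-numbered pairs had a correlation over 0.1 (range -0.133 to 0.138) and 3 of 9 libraries correlated best with their own number. These correlations over all genes also carry the GC trends of single libraries, so they cannot exclude that same-numbered libraries were handled together. No paired analysis was possible because the ISRIB-only columns carry no usable number, for the comparisons with that group, the interaction and the A8 effect with ISRIB.

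When 1 library was left out, counts ranged from 10 to 14 higher and 3 to 7 lower in A8 against vehicle, 0 to 1 and 0 to 2 with ISRIB alone, 0 to 3 and 0 to 4 with both, 0 to 5 and 0 to 8 in A8 with ISRIB against ISRIB alone, 2 to 4 and 14 to 29 against A8, and 0 to 3 and 0 to 3 in the interaction. A lone ISRIB-only library was then assumed to vary like the other groups. The interaction of the regulators list ranged from -0.1836 to -0.0559 and lost its call without DMSO 3, DMSO with ISRIB b, A8 1 or A8 with ISRIB 1 (adjusted p from 0.066 to 0.162). With an estimated correlation the interaction calls of the pool (-0.2273), synthesis (-0.3101), transport (-0.3007) and regulators (-0.1172) were lost, and by fry that of regulators (-0.1172). Ribosomal proteins with both compounds turned to -0.0354 without DMSO 3 and to -0.0309 without A8 with ISRIB 3, from 0.0539, with a highest value of 0.1235 without A8 with ISRIB 1.

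The median with ISRIB of the genes called higher with A8 ranged from 0.0432 to 0.194 and that of the lower genes from -0.2835 to 0.0725 with 1 library left out, turning positive without DMSO 2 (0.0725), A8 1 (0.0455), A8 2 (0.0723) or A8 3 (0.0302), where fewer genes were called lower. For the lower genes it was -0.052 without a filter, -0.1905 with the GC trend removed and -0.1141 without DMSO 1 and DMSO with ISRIB b. The Pearson correlation was 0.0372 without a filter, 0.1509 with the GC trend removed and 0.0172 to 0.1337 with 1 library left out, and the Spearman 0.1598 with the GC trend removed and -0.0114 to 0.092 with 1 library left out. The pseudocount alternatives were fixed for normalized units and were not run because the table holds counts. No prior count other than 2 was tried for the list tests. Depth limits what a count of 0 excludes, which is up to 0.0881 CPM for IFNB1. DDX58 and IFIT1 had 54 to 122 counts per library, and counting error was not separated from the spread between libraries for them.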

Other observations

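The tests of GC content for TXNIP and of genes with 0 counts were chosen after the results were seen. That of MondoA targets followed from the fall of TXNIP, and its genes were fixed before the test. Transcripts encoded by mitochondrial DNA were higher with A8 as a list, with a median log2 fold change of 0.38 and 13 of 13 members above 0, none of them called over all genes tested and 4 higher adjusted over the list alone. The camera adjusted p was 3.56e-05, a call lost with an estimated correlation (adjusted p = 0.375). CYTB had a log2 fold change of 0.52 and ND5 one of 0.50. The median was 0.30 in A8 with ISRIB against ISRIB alone (camera adjusted p = 0.00384, lost likewise, adjusted p = 0.621). Mitochondrial mRNA made up 7.97%, 7.39% and 9.74% of counts in the vehicle libraries, 10.0% and 8.08% with ISRIB alone, 10.7%, 9.31% and 11.1% with A8, and 9.39%, 9.74% and 12.6% with both.

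Genes of sterol synthesis, driven by SREBP, were lower with A8 with a median of -0.12 and 17 of 19 members below 0 (camera adjusted p = 3.68e-05, lost with an estimated correlation, adjusted p = 0.0983). MVD had a log2 fold change of -0.22 and no member was called. The list of the aryl hydrocarbon receptor was lower with a median of -0.36 over 4 genes (camera adjusted p = 0.0224, lost likewise, adjusted p = 0.0983). Immediate early genes had a median of -0.03 with A8 (camera adjusted p = 0.52) and were higher in A8 with ISRIB against A8 (median 0.07, camera adjusted p = 0.00149, and adjusted p = 0.0289 with an estimated correlation). Camera adjusted p-values in A8 against vehicle were 0.829 for mitochondrial chaperones, 0.191 for hypoxia, 0.197 for metal response, 0.363 for cell cycle, 0.137 for ribosomal proteins and 0.363 for replication histones.

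TXNIP was lower with A8 without ISRIB and with it, in comparisons that share no library. With the GC trend removed, its log2 fold change with ISRIB was -1.327 (SE 0.17, adjusted p = 0.00808 in edgeR) against -1.37 before, so that trend is not the whole cause. ARRDC4 had log2 fold changes of -0.68 and -0.82, the second not called (adjusted p = 0.0584). A hypothesis is lower activity of MondoA and ChREBP, glucose-responsive factors that drive TXNIP. The other targets measured, 8 of 11 fixed before the test, had a median of -0.005 in A8 against vehicle, ranging from -0.08 to 0.09 with 5 of 8 below 0, and one of 0.02 with ISRIB. Members that go both ways give the hypothesis no backing, and the lack of a call for so few genes does not exclude it.

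In 9 genes some libraries had 0 counts while the median of the others was 50 or more. Among the 7 with another gene of overlapping name, the partners gained a median of 0.891 of what was lost, as when reads go to one or the other of overlapping gene models. The range was wide, from -0.267 for CORO7-PAM16, whose partners were lower rather than higher, to 1.61 for ASB3. NBL1, for example, was at 0 in DMSO with ISRIB a, DMSO with ISRIB b and A8 with ISRIB 3, where MINOS1-NBL1 was higher by 14.1 CPM against a loss of 15.2 CPM. NBL1, KTI12 and P2RY11 were at 0 in every library of some group. For 0 of the 9 genes, though, were the libraries at 0 made up of whole groups alone, so that each gene was at 0 in part of at least 1 group, which argues against treatment as the whole cause.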
